A study of Homo sapiens with 4 samples.

How the data were processed

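Total RNA from 2 human lung cancer cell lines, H1299 and HCC827, was sequenced 48 h after transfection with an siRNA against CDH3 (siCDH3) or a control siRNA (siCTR). The labels give 4 libraries in 4 groups, with 1 library per group. RNA was extracted with a commercial reagent and libraries followed a standard Illumina protocol, per the labels' protocols. The siRNA sequences, the aligner, the counting tool, the strandedness and the read depth are not given in the sources used here.

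The authors deposited a table of TPM values, a length-scaled measure of transcript abundance, for 58174 genes, with 1 column per library and no pooling. Each column is named in the labels of 1 library, and no other column of values was left aside. TPM divides reads by transcript length and scales each library to a fixed sum, so values are relative within a library and keep no depth. For that reason no counting interval or detection floor can be given, and precision at low TPM is unknown. The genome build named in the submitters' processing notes is hg19. Of the gene identifiers in the table, 57836 of 58174 (99.4%) are in GENCODE release 29, which is built on a later assembly, so no coordinates are printed. That annotation was used here only for gene types, transcript lengths, GC content, read-through genes and 3' UTR sequences.

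Within each line the log2 ratio of TPM + 1 was taken, siCDH3 over siCTR, for genes with a TPM of at least 5 in at least 1 of the line's 2 libraries. The pseudocount of 1 understates the change of genes with low TPM. Genes with a log2 ratio of at least 1 or of -1 or lower (2-fold on the TPM + 1 scale) were counted. With 1 library per group no p-value was computed within a line, and no difference within a line has a replicate check. Genes past the size rule in both lines were counted beside the number expected of independent lists (n1 × n2 / N) with its 95% Poisson range. The 2 lines share no library.

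The 39 gene lists, with 952 gene entries that were all matched in the table, covered classical cadherins and catenins, desmosomes and tight junctions, epithelial and mesenchymal state, adhesion, proteases, the cell cycle, signalling targets, interferon and inflammation, stress responses, metabolism, ribosomes, histones, apoptosis, and markers of other cell types. The result of each list in each line is printed in the report. For a list with at least 5 members past the filter, the median log2 ratio was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list outside the central 95% band of these medians was counted. This describes the libraries and is not a test of the treatment. Random lists were drawn gene by gene, so lists whose members vary together between cultures can lie outside the band more often.

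limma (version 3.58.1, R 4.3.3) was fitted to log2(TPM + 1) of the 12941 genes with a TPM of at least 5 in at least 1 of the 4 libraries, with cell line as a block and siRNA as the term of interest. Here the cell line is the unit of replication (2 lines, 1 residual degree of freedom per gene). The pairing comes from the labels, which name the line of each library. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The spread in this test is the difference between the responses of the lines, not the spread within a line.

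The names given in the text follow a rule. They are CDH3, CDH1 and CDH2, the 10 highest and 10 lowest log2 ratios per line among protein-coding genes with an official symbol, up to 10 genes per direction changed in both lines, up to 4 genes changed in opposite directions, and up to 4 members with the largest log2 ratios in each list described. Some genes that this rule takes are not reported here. Any other name is said to have been chosen after its values were seen. The lists, the limma fit, this rule and most alternatives were fixed before the data were examined, and some tests of explanations were chosen after.

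Alternatives were pseudocounts of 0.1 and 5, filters at TPM 1 and TPM 20 and no filter, a median log2 ratio set to 0 within each line, TPM recomputed over nuclear protein-coding genes without ribosomal protein genes, quantile normalization, size rules of 1.5-fold and 4-fold, list means in place of medians, a minimum of 10 members per list, and limma without the block, with a trend and without each library. Leaving out read-through genes was added after the data were examined.

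The scripts were tested on simulated data. In the limma comparison over 12941 genes, 200 genes were given known changes. limma recovered 100% of the 2-fold and 100% of the 4-fold genes, with 12 false calls. Every simulated gene of a line had the same spread, and each change was the same in both lines. This recovery therefore does not give the power in the data, where MXD1, at log2 ratios of -2.46 and -2.23, did not pass. In simulated unchanged ratios for the 11622 genes of H1299 and the 11043 genes of HCC827, 0 lists in each lay outside the band, and a list shifted by 0.2 lay at percentile 100 in each. For the words over both lines, an 8-base site was picked. The simulated ratios of the 1983 among 8996 genes with a match to its first or last 7 bases were shifted by -0.2, and it was ranked 1. That shift is larger than the means of -0.05 and -0.06 reported below for the 291 genes with all 8 bases of the lowest word. The search per line was not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.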

Results

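Gene expression was measured by RNA sequencing in H1299 and HCC827 cells, 48 h after transfection with siCTR or siCDH3. H1299 is a non-small cell lung cancer line taken from a lymph node metastasis, and HCC827 is a lung adenocarcinoma line with an activating EGFR deletion. CDH3 encodes P-cadherin, a classical cadherin of epithelial cell junctions. The design asked which genes differ in expression when CDH3 is silenced for a short time in each line. There were 4 groups with 1 library each. The read depth is unknown, because the values are TPM. In each library the TPM column summed to between 999859 and 999943. Genes with a TPM of at least 5 numbered 11329 in H1299 siCTR, 11103 in H1299 siCDH3, 10713 in HCC827 siCTR and 10780 in HCC827 siCDH3. Mitochondrially encoded protein-coding genes took 10.1% of TPM in H1299 siCTR, 12.8% in H1299 siCDH3, 27.6% in HCC827 siCTR and 26.4% in HCC827 siCDH3. Across 12941 genes, Pearson's r of log2(TPM + 1) was 0.979 between the libraries of H1299 and 0.984 between those of HCC827, and lay between 0.606 and 0.615 for libraries of different lines. These correlations are across genes, which are not independent replicates.

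CDH3 (ENSG00000062038), the targeted gene, was lower in the siCDH3 library of both lines. In HCC827 its TPM was 173 in siCTR and 78.8 in siCDH3, a log2 ratio of -1.12, which left 45.6% of the control level. In H1299 it was 1.21 in siCTR and 0.169 in siCDH3, 7.16-fold lower, from a level that was low before silencing. The log2 ratio in H1299 was -0.92 on the TPM + 1 scale. Because both H1299 values are under the filter of 5 TPM, the size of that ratio depends on the pseudocount, and it was -2.28 with a pseudocount of 0.1. Before silencing, CDH3 TPM was 143-fold higher in HCC827 than in H1299. Among filtered genes of HCC827, 68 had a lower log2 ratio than CDH3.

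CDH1 and CDH2 marked the lines apart. CDH1 (E-cadherin, the main epithelial cadherin) had a TPM of 322 in HCC827 siCTR and 439 in HCC827 siCDH3, a log2 ratio of 0.45, and was at 0.0495 and 0.0345 in H1299. CDH2 (N-cadherin, typical of mesenchymal cells) had a TPM of 35.3 in H1299 siCTR and 22.7 in H1299 siCDH3, a log2 ratio of -0.61, and was listed at 0 in both HCC827 libraries.

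**Figure D1:**
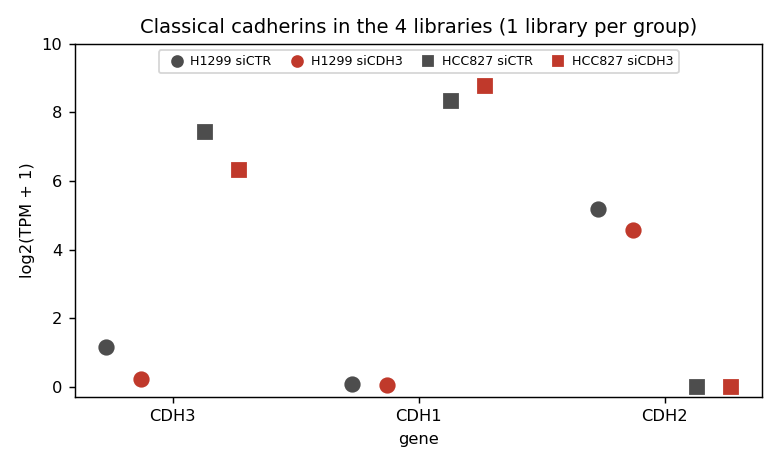
Level of CDH3, CDH1 and CDH2 in each of the 4 libraries, as log2(TPM + 1) on the vertical axis, with 1 point per library (circles H1299, squares HCC827, grey siCTR, red siCDH3) and no error bars because each group has 1 library. CDH3 is lower in siCDH3 than in siCTR in both lines, with log2 ratios of -0.92 in H1299 and -1.12 in HCC827.

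The control libraries were compared to describe the lines before silencing. Of 24 genes of the epithelial state list, 22 were at least 2-fold higher in HCC827 siCTR than in H1299 siCTR, with a list median log2 ratio of 4.59. Of 24 genes of the mesenchymal state list, 13 were at least 2-fold lower in HCC827 and 1 was higher, with a median of -1.90. Keratin 7 (KRT7) had a TPM of 1214 in HCC827 siCTR and 5.49 in H1299 siCTR, and the transcriptional repressor ZEB1 had 0.250 and 34.7. Over all 12601 genes compared, 1695 were at least 2-fold higher and 3500 at least 2-fold lower in HCC827, and the median log2 ratio was -0.39. Mitochondrially encoded protein-coding genes took 27.6% of TPM in HCC827 siCTR and 10.1% in H1299 siCTR. Because each library sums to a fixed total, that lowers the TPM of all other genes in HCC827. The counts were not centred for this, so their split is not read as a difference of the lines. Markers of other cell types stayed low: 1 of 20 hematopoietic markers and 1 of 12 endothelial markers reached a TPM of 5 in each library, and of 15 fibroblast markers 2 did so in H1299 siCTR and 1 in each of the others. These values come from 1 library per line and have no replicate check.

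In H1299, siCDH3 went with lower TPM of TNFRSF6B, which encodes decoy receptor 3, a soluble receptor that binds FAS ligand. Its TPM was 80.8 in siCTR and 0.00849 in siCDH3, a log2 ratio of -6.34. MXD1, a repressor in the MYC and MAX network, went from 10.1 to 1.01 (-2.46). The trans-Golgi protein gene TGOLN2 had 83.5 in siCTR and 8.11 in siCDH3 (-3.21), and the Mediator subunit gene MED29 had 133 and 24.3 (-2.41). Other lower genes were C11orf57 (-2.79), ZNF607 (-2.45), the small GTPase gene RHOQ (-2.32) and BANF1 (-2.21), whose product binds DNA and the nuclear lamina.

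Higher in siCDH3 H1299 were the neuropeptide precursor gene VGF, with a TPM of 49.8 in siCTR and 210 in siCDH3 (log2 ratio 2.06), and CHAC1, a glutathione-degrading enzyme gene induced by ATF4, with 2.53 and 13.6 (2.05). The mitochondrial ribosomal protein gene MRPL34 (30.4 and 134.5 TPM, 2.11), the protocadherin gene PCDHGA3 (9.45 and 56.8, 2.47), RUNDC3A (0.846 and 8.37, 2.34) and the sulfurtransferase gene MPST (18.6 and 77.4) were also higher. Read-through genes, which join the exons of neighbouring genes, were among both ends. C7orf55-LUC7L2 (3.61), NEDD8-MDP1 (3.49), SENP3-EIF4A1 (2.91) and URGCP-MRPS24 (2.61) were higher, and MINOS1-NBL1 (-4.16) and ATP6V1G2-DDX39B (-3.08) were lower. TPM of such genes and of genes that overlap them, TNFRSF6B, ZNF607, CTNND1, IRF9 and RRM2 among them, is uncertain, because reads of shared exons can be given to either gene.

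Over the 11622 genes tested in H1299, 102 were at least 2-fold higher and 184 at least 2-fold lower in siCDH3, so that 64.3% of them were lower. The median log2 ratio of all genes was -0.11. With that median set to 0 the split became 140 higher and 134 lower, 48.9% lower. Changes of gene lists in H1299 are therefore also given relative to the median of all genes. No difference in this line has a replicate check.

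Of the lists compared in H1299, 5 of 34 lay outside the band of matched random lists, where 1.7 would do so if members varied independently. Interferon response genes were higher in siCDH3, with 26 of 28 members above the median of all genes, a list median of 0.23 (0.34 above all genes) and percentile 100. IFI27 had a TPM of 2.48 in siCTR and 6.81 in siCDH3, the antiviral membrane protein gene BST2 5.83 and 12.3, the transcription factor gene IRF9 43.3 and 84.8, and IFI44L 3.67 and 7.85. Of the list, 1 member was past the 2-fold rule. Classical cadherins and catenins were lower, with 8 of 12 members below the median of all genes, a list median of -0.37 (-0.26 relative to all genes) and percentile 0.12. CTNND1, which encodes the cadherin-stabilising p120-catenin, had a TPM of 82.2 in siCTR and 23.3 in siCDH3, and CTNNA1 (alpha-catenin) 312 and 164. NECTIN2 went the other way, with 225 and 321.

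DNA replication and S phase genes were lower in siCDH3 H1299, with 22 of 31 members below the median of all genes, a list median of -0.26 (-0.16 relative to all genes) and percentile 1.15. The DNA polymerase alpha gene POLA1 had a log2 ratio of -0.60, the ribonucleotide reductase gene RRM2 -0.58, GINS1 -0.57 and the histone mRNA-binding protein gene SLBP -0.50. Mitochondrially encoded genes were higher for 13 of 13 members, with a median of 0.28 (0.39 above all genes) and percentile 100, led by MT-ATP6 (1.82) and MT-ND6 (0.60). Replication-dependent histones had a median of 0.10 and percentile 97.7, with HIST1H2BG at 0.61 and HIST1H2AG at -0.57. The S phase call ended with list means (percentile 4.44) and with TPM over nuclear protein-coding genes (2.57), the cadherin call with no filter (54.4), and the histone call in 6 settings. A trend on transcript length and GC content took 9.89% of the variance of the log2 ratios in H1299. Of the 5 lists, 4 stayed outside the band after its removal, all but the histones, and 9 lists in all then lay outside. Newly below it were fatty acid synthesis (percentile 0.11), YAP and TEAD targets (0.78) and integrins and focal adhesion (1.815). Newly above it were ribosome biogenesis and MYC targets (97.84) and nuclear genes of oxidative phosphorylation (98.22).

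The other lists compared in H1299 lay inside the band before removal of the length and GC trend, which put some of them outside, as named above. For adhesion and cell state, the percentiles were 28.0 for desmosomes and tight junctions, 92.0 for epithelial state, 34.0 for mesenchymal state, 5.31 for extracellular proteases and their inhibitors, 14.3 for integrins and focal adhesion and 80.7 for the S100 family. For growth control they were 20.4 for mitosis and G2/M, 6.45 for CDK inhibitors and quiescence, 40.8 for p53 targets and 8.70 for apoptosis regulators. For signalling they were 10.2 for beta-catenin and TCF targets, 7.67 for YAP and TEAD targets, 88.2 for TGF-beta and SMAD targets, 21.1 for ERK feedback and EGFR ligands, 63.3 for immediate early genes, 79.2 for antigen presentation and 88.2 for NF-kB targets and inflammatory cytokines. For stress they were 85.7 for the unfolded protein response and ATF4 targets, 16.7 for heat shock and proteotoxic stress, 26.9 for NRF2 targets and 57.1 for autophagy and lysosome. For metabolism and translation they were 30.7 for cholesterol synthesis and uptake, 6.20 for fatty acid synthesis, 12.2 for glycolysis and hypoxia, 97.4 for nuclear genes of oxidative phosphorylation (above the band in 6 alternatives, at 98.0 to 99.4), 74.6 for cytosolic ribosomal proteins, 88.3 for ribosome biogenesis and MYC targets, 61.9 for RNA interference machinery and 4.91 for housekeeping genes. Hematopoietic, fibroblast, endothelial, lung epithelial lineage and squamous and basal keratinocyte markers had fewer than 5 measured members.

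In HCC827, B2M, the light chain of MHC class I, had a TPM of 86.3 in siCTR and 896 in siCDH3, a log2 ratio of 3.36. TNFRSF6B had 108 in siCTR and 0.00493 in siCDH3 (-6.76), and MXD1 had 10.7 and 1.51 (-2.23). CLDN4, a tight junction claudin, was lower in siCDH3, with 164 and 14.4 (-3.42), as was DAG1 (dystroglycan, a laminin receptor) with 55.1 and 7.52 (-2.72). NKRF (NF-kB repressing factor) had 26.8 and 3.74 (-2.55) and MRPL34 had 89.4 and 21.5 (-2.01). The kinase gene UHMK1 (-1.90) and MRFAP1 (-1.88) were also lower.

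Higher in siCDH3 HCC827 were the DNA exonuclease gene TREX1, with a TPM of 0.562 in siCTR and 6.75 in siCDH3 (2.31), TRIM52 (2.15), TGIF2 (1.94), a repressor of TGF-beta targets that overlaps a read-through gene, MEX3C (1.81), TMEM198 (1.75) and TNFAIP1 (1.75). Of read-through genes, PRR5-ARHGAP8 (2.59), SENP3-EIF4A1 (2.47) and ST20-MTHFS (2.41) were higher and C7orf55-LUC7L2 (-3.19) was lower. Over 11043 genes tested, 111 were at least 2-fold higher and 92 at least 2-fold lower in siCDH3. The median log2 ratio of all genes was 0.03, and with it set to 0 the split was 104 higher and 101 lower. No difference in this line has a replicate check.

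Of the lists compared in HCC827, 10 of 36 lay outside the band, where 1.8 would do so if members varied independently. NF-kB targets and inflammatory cytokines were higher in siCDH3, with 21 of 23 members above the median of all genes, a list median of 0.38 and percentile 100. The cyclooxygenase gene PTGS2 had a TPM of 39.1 in siCTR and 91.0 in siCDH3, the neutrophil chemokine genes CXCL1 334 and 573 and CXCL8 198 and 332, and the cytokine gene IL1A 56.7 and 85.3. Interferon response genes were higher for 29 of 35 members (median 0.14, percentile 99.9), with SAMD9L at 4.84 and 13.5 TPM, TRIM22 at 3.76 and 6.57, OAS2 at 23.2 and 31.3, and MX1 at 68.5 and 86.0. Antigen presentation genes were higher for 18 of 20 members (median 0.13, percentile 99.3). Beside B2M these were CD274, which encodes the checkpoint ligand PD-L1, with 3.19 and 9.81, the MHC class I activator gene NLRC5 with 9.72 and 14.8, and HLA-B with 239 and 324.

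Integrins and focal adhesion genes were higher in siCDH3 HCC827, with 15 of 20 members above the median of all genes, a list median of 0.19 and percentile 99.97. LIMS1 had a log2 ratio of 0.91, the zyxin gene ZYX 0.58, the talin gene TLN1 0.45 and ITGB5 0.40. Apoptosis regulators had 18 of 26 members above (median 0.14, percentile 99.5), with PMAIP1 (0.83), BID (0.67) and BAD (0.49), which promote cell death, higher and the survival gene BCL2L2 (-0.92) lower. Replication-dependent histones had 8 of 9 members above (median 0.25, percentile 99.7), HIST1H2BC at 0.54 and HIST1H2BD at 0.47.

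Proliferation genes were lower in siCDH3 HCC827. DNA replication and S phase genes had 27 of 30 members below the median of all genes, a list median of -0.20 and percentile 0, which is below all 10000 random lists. UHRF1 had a TPM of 10.1 in siCTR and 6.97 in siCDH3, ORC1 12.2 and 9.71, and PRIM1, which overlaps a read-through gene, 18.6 and 15.2. Mitosis and G2/M genes had 32 of 36 members below (median -0.16, percentile 0), with AURKB at -0.34, KIF20A at -0.33 and CDK1 at -0.32, whereas FOXM1, a transcription factor of mitotic genes, was higher at 0.91. The unfolded protein response and ATF4 list was lower (22 of 30 members below, median -0.07, percentile 0.04), with HERPUD1 at -0.61, although TRIB3 was higher, at 103 TPM in siCTR and 206 in siCDH3. Mitochondrially encoded genes were lower for 13 of 13 members relative to the median of all genes (median -0.06, percentile 2.04). With quantile normalization the median was 0. That method gives a gene of equal rank in both libraries the same value, so this 0 says little of the direction. The apoptosis call ended with a filter at TPM 20 (percentile 82.3) and a pseudocount of 5 (96.0), the histone call with a filter at TPM 20 (93.5) and the unfolded protein response call with list means (9.26). The trend on transcript length and GC content took 0.245% of the variance in HCC827, and 10 of the 10 lists stayed outside the band after its removal.

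**Figure D2:**
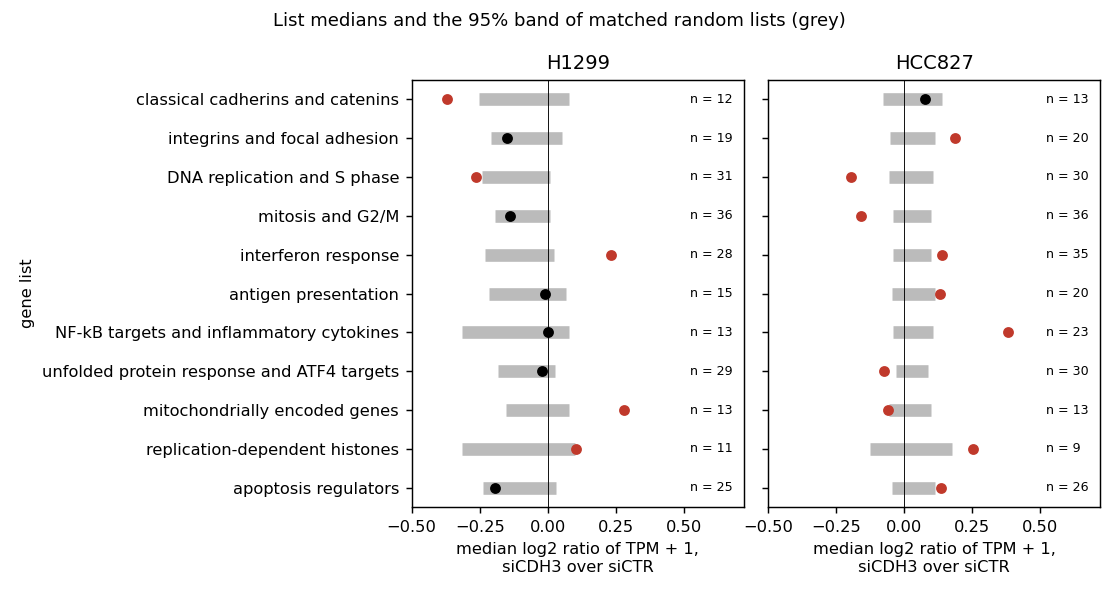
Median log2 ratio of TPM + 1 (siCDH3 over siCTR) on the horizontal axis for the gene lists outside the band in at least 1 line, with n the members measured, 1 library per group and the central 95% of 10000 matched random lists as grey bars. Red points lie outside the band and black points inside; interferon response lies above it in H1299 (0.23) and in HCC827 (0.14), and DNA replication and S phase below it in H1299 (-0.26) and in HCC827 (-0.20).

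The other lists compared in HCC827 lay inside the band. For adhesion and cell state, the percentiles were 82.8 for classical cadherins and catenins, 29.1 for desmosomes and tight junctions, 37.6 for epithelial state, 76.4 for mesenchymal state, 94.3 for extracellular proteases and their inhibitors, 51.6 for the S100 family, 94.6 for squamous and basal keratinocyte markers and 89.8 for lung epithelial lineage markers. For growth control they were 76.5 for CDK inhibitors and quiescence and 36.0 for p53 targets. For signalling they were 84.4 for beta-catenin and TCF targets, 14.4 for YAP and TEAD targets, 45.2 for TGF-beta and SMAD targets, 89.1 for ERK feedback and EGFR ligands and 52.6 for immediate early genes. For stress they were 11.1 for heat shock and proteotoxic stress, 28.9 for NRF2 targets and 77.8 for autophagy and lysosome. For metabolism and translation they were 92.9 for cholesterol synthesis and uptake, 67.8 for fatty acid synthesis, 95.9 for glycolysis and hypoxia, 54.98 for nuclear genes of oxidative phosphorylation, 45.7 for cytosolic ribosomal proteins, 69.2 for ribosome biogenesis and MYC targets, 76.7 for RNA interference machinery and 96.9 for housekeeping genes. Hematopoietic, fibroblast and endothelial markers had fewer than 5 measured members.

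The lines were then compared to ask which genes responded alike. TNFRSF6B, MXD1 and JPT2 were lower in both lines, JPT2 with log2 ratios of -1.92 in H1299 and -1.81 in HCC827. TAX1BP3, a PDZ protein gene, had -1.60 and -1.55, the microtubule-associated protein gene MAP1S -1.54 and -1.52, and MPI, the mannose phosphate isomerase gene, -1.91 and -1.30. FAM102A, ZNF358 and VAPA, an endoplasmic reticulum contact-site protein gene, were also past the rule in both. Higher in both were TMEM198 (1.98 and 1.75), TNFAIP1 (1.46 and 1.75), RUNDC3A (2.34 and 1.36), ABHD14B (1.34 and 1.38), TMEM251 (1.21 and 1.60), ZBTB43 (1.13 and 1.57), UBE2V2 (1.35 and 1.08), TMEM164 (1.05 and 1.59), SENP3-EIF4A1, and the methylglyoxal-detoxifying enzyme gene GLO1, whose TPM was 108 and 259 in H1299 and 53.8 and 125 in HCC827.

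Of 9724 genes tested in both lines, 13 were at least 2-fold higher in both, where independent lists would share 0.587 (95% Poisson range 0 to 2), and 13 were at least 2-fold lower in both, where 1.18 would be shared (0 to 4). Across these 9724 genes Spearman's rank correlation between the log2 ratios of the lines was 0.0928. This correlation is across genes, which are not independent replicates. Of the 26 genes changed alike, 13 (50%) were read-through genes or overlapped one on the same strand, against 7.89% of the genes tested in both lines. TNFRSF6B, JPT2, TAX1BP3, ZNF358, ABHD14B and TMEM251 were among these. Without all such genes, a setting chosen after the data were examined, the counts were 8 higher and 5 lower, with 10 genes in opposite directions.

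**Figure D3:**
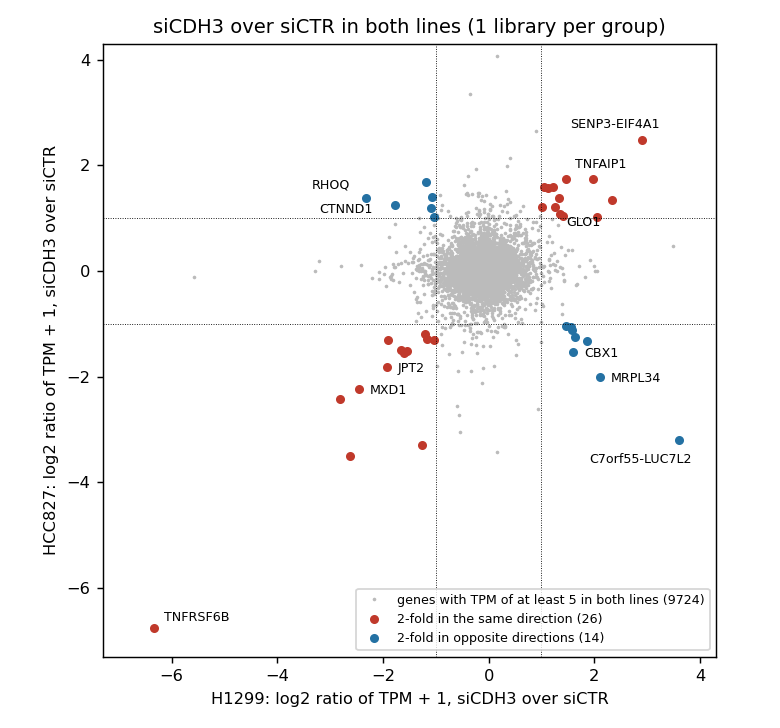
Log2 ratio of TPM + 1 (siCDH3 over siCTR) in H1299 on the horizontal axis and in HCC827 on the vertical axis for the 9724 genes tested in both lines, 1 point per gene, with dotted lines at the 2-fold rule. Red points are the 26 genes past the rule in the same direction, with TNFRSF6B at -6.34 and -6.76, and blue points the 14 past it in opposite directions.

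Other genes were past the size rule in opposite directions. CBX1, a heterochromatin protein gene, had a log2 ratio of 1.60 in H1299 and -1.53 in HCC827, and RHOQ had -2.32 and 1.39. CTNND1, which overlaps a read-through gene, was lower in H1299 (-1.78) and higher in HCC827 (1.24), where its TPM was 67.9 in siCTR and 162 in siCDH3. In all 14 genes went in opposite directions, 8 of them higher in H1299 and 6 higher in HCC827, against 0.531 and 1.30 expected of independent lists. Among the 40 genes past the rule in both lines, 26 (65.0%, exact 95% interval 48.3 to 79.4) went in the same direction, which did not differ from an even split (exact binomial test, two-sided p = 0.0807). That test takes genes as independent, which genes of the same libraries are not, and some of them share exons. Its interval and p therefore do not measure the spread of the response between lines. Of the lists compared, interferon response lay above the band in both lines, as did replication-dependent histones, and DNA replication and S phase lay below it in both. The histone call ended in 6 settings in H1299 and with a filter at TPM 20 in HCC827. The S phase call in H1299 ended with list means and with TPM over nuclear protein-coding genes. Whether the lines differ in any 1 gene was not tested, as each arm is 1 library.

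With the line as the unit of replication, limma called 1 of 12941 genes. TNFRSF6B fell by 6.55 on the log2 scale on average over the lines (SE 0.178, 2 lines, lower in both; limma, Benjamini-Hochberg adjusted p = 0.00733). At an unadjusted p under 0.05 there were 581 genes. Next among the genes named here were SENP3-EIF4A1 (mean log2 ratio 2.69, SE 0.180) and MXD1 (-2.34, SE 0.159). Both had a limma adjusted p of 0.132, which did not pass. The targeted gene CDH3 did not pass either (mean log2 ratio -1.02, SE 0.157, limma adjusted p = 0.682). Without the cell line block, 0 genes were called, with 20 at an unadjusted p under 0.05. The call also ended with no filter on low values, with TPM over nuclear protein-coding genes and with quantile normalization, and reads of TNFRSF6B can be given to RTEL1-TNFRSF6B, a read-through gene named here after its values were seen, whose TPM was 7.08 in siCTR and 15.2 in siCDH3 H1299, and 4.56 and 11.9 in HCC827.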

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

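The tests of the overlap against independent lists, of the overlap without read-through genes, of the share of genes that changed alike, of sums with read-through genes and of the size of the length and GC trend were chosen after the result was seen, and the other tests in this part before.

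Some results stood out because the lines went in opposite directions, a difference that was not tested because each arm is 1 library. In all, 14 genes were past the 2-fold rule in opposite directions. The difference of the log2 ratios, HCC827 minus H1299, was -6.80 for C7orf55-LUC7L2, -4.12 for MRPL34, -3.14 for CBX1 and 3.71 for RHOQ. C7orf55-LUC7L2 is a read-through gene. Its sum with LUC7L2, named after its values were seen, was lower in both lines, from 95.6 to 82.8 TPM in H1299 and from 68.1 to 55.2 in HCC827. LUC7L2 alone went from 95.6 to 71.6 TPM in H1299 and from 59.9 to 55.2 in HCC827. Because LUC7L2 makes up most of the sum, the sum cannot show whether the opposite direction came from how reads were assigned. For the list of mitochondrially encoded genes, above the band in H1299 and below it in HCC827, the difference of the medians was -0.34. The list's median in HCC827 was 0 with quantile normalization, which gives a gene of equal rank in both libraries the same value.

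The genes with the largest log2 ratios included many read-through genes and genes that overlap one. A wide choice of isoform lengths was not enriched in the 2-fold genes, since 66.3% of those of H1299 have transcripts that span more than 4-fold in length (matched genes 62.8% to 73.7%) and 66.5% of those of HCC827 (63.5% to 76.4%). Read-through genes and genes overlapping one made up 21.1% of the 2-fold genes in H1299 (matched genes 5.61% to 12.3%) and 24.1% in HCC827 (4.93% to 12.8%), so reads given to either of 2 overlapping genes may account for part of the 2-fold changes, and for part of the fall of TNFRSF6B: its sum with RTEL1-TNFRSF6B went from 87.9 to 15.2 TPM in H1299 and from 112 to 11.9 in HCC827, but that gene's annotated transcripts are 5.04-fold longer, and with TPM weighted by length 65.8% and 45.8% of the sum were left. The overlap of the lines is larger than independent lists would give, with 13 genes lower in both against 1.18. Read-through genes do not account for all of it. Without such genes 5 were lower (0.809 expected, Poisson range 0 to 3) and 8 higher (0.398, 0 to 2). In that setting 10 genes went in opposite directions, for which no expected number was computed. A response to CDH3 silencing common to the lines and an effect of an siRNA on other transcripts, taken up below, stay open. So do a difference in handling between the siCTR and siCDH3 libraries, and chance in genes whose values vary more than others in both lines. These cannot be told apart with 1 library per group. CDH3 was at 1.21 TPM in H1299 siCTR, against 173 in HCC827 siCTR. With all genes kept, 8 and 6 genes went in opposite directions, against 0.531 and 1.30 for independent lists. Of the 40 genes past the rule in both lines, 65.0% changed alike, in an interval that includes an even split but takes genes as independent.

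DNA replication and mitosis genes were lower in siCDH3 HCC827. A trend on transcript length and GC content between the libraries is argued against by its size, because it took 0.245% of the variance in HCC827 and its lowest value at any member was -0.0386, against list medians of -0.20 and -0.16; its removal left both lists at percentile 0 of matched random lists but moved values little, so it adds little. The lists were called on medians, which a few members cannot carry. Of their 66 members, 89.4% lay below the median of all genes, a share that partly restates the call. In H1299 the share was 62.7% of 67 members, and the mitosis list lay inside the band. Slower proliferation after CDH3 silencing may be one explanation in HCC827, as a hypothesis. However, FOXM1 was higher (0.91), and replication-dependent histones, made in S phase, were above the band (median 0.25, percentile 99.7). The histone list had 9 of 18 members measured and lay inside the band with a filter at TPM 20 (93.5). Whether its rise bears on growth was not tested. A difference in cell density or growth between 2 dishes would look the same as an effect of silencing, and no replicate culture separates them. Cell counts or DNA synthesis in replicate cultures seeded alike would test slower proliferation.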

How the results depend on the processing

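Leaving out read-through genes was chosen after the result was seen. Every setting kept the direction of CDH3, with a log2 ratio in H1299 of -1.14 over nuclear protein-coding genes, -2.28 with a pseudocount of 0.1 and -0.26 with a pseudocount of 5. Counts over 1.5 times off the main count were as follows, higher then lower. With 1.5-fold they were 373 and 826 in H1299, 370 and 280 in HCC827, and 38 and 60 in both lines. With 4-fold they were 12 and 26, 15 and 18, and 1 and 4. A filter at TPM 1 gave 228 and 308, 193 and 180, 22 lower in both lines and 30 opposite genes, and no filter gave the same counts, 228 and 308, 193 and 180, 22 and 30. A filter at TPM 20 gave 43 and 108, 50 and 48, 6 and 8 in both lines and 6 opposite. A pseudocount of 5 gave 47 and 91, 53 and 46, 4 higher in both lines and 7 opposite. These follow from the rule itself or from fewer or more genes tested. Without read-through genes 8 and 5 were shared, and the counts per line stayed within 1.5 times. Lists outside the band in H1299 numbered 3 over nuclear protein-coding genes and 9 with a filter at TPM 20; the cause was not tested. limma called 0 genes with no replicate block, with no filter, over nuclear protein-coding genes (20, 1318 and 588 at an unadjusted p under 0.05) and with quantile normalization (640), with a smallest adjusted p from 0.0648 to 1. It called 0 without each of the 4 libraries (10 to 17 unadjusted), in fits without the block because the blocked fit leaves no residual degree of freedom; in the settings that kept it, the smallest adjusted p ran from 0.00261 to 0.0211. The median of mitochondrially encoded genes in HCC827 was 0 with quantile normalization, because that method gives a gene of equal rank in both libraries the same value. Of the 26 genes changed alike, 14 were past the rule under each pseudocount and scaling and each filter but that at TPM 20. Of 816 values of named genes, 799 kept their side of the rule, 16 lost it and 1 gained it. The filter settings do not alter a gene's log2 ratio, so their values among the 816 could not move and are no check. Of 147 values of lists outside the band, 133 stayed outside and 13 moved inside. The other 1 was the median of 0 of mitochondrially encoded genes. Of 537 values of the 55 list results inside the band, 20 moved outside, in 13 list results, 6 of them for nuclear genes of oxidative phosphorylation in H1299. With a line's median set to 0, or a minimum of 10 members, the percentile of a list still compared cannot change. Such values, inside or outside the band, are therefore no check. Between the control libraries, HCC827 over H1299, the median of the epithelial state list was 7.31 with a pseudocount of 0.1, 3.81 with a pseudocount of 5 and 5.58 over nuclear protein-coding genes, and that of the mesenchymal state list -2.61, -1.09 and -1.56. Depth is unknown in TPM, so its limit on low genes such as CDH3 in H1299 cannot be given.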

Other observations

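The tests of the words most extreme over both lines, in the CDH3 siRNA, control siRNA and base composition, were chosen after the result was seen, and the search for words in each line before.

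Members of lists that stayed inside the band also differed between the libraries. In H1299 the metastasis-associated calcium-binding protein gene S100A4 had a TPM of 48.9 in siCTR and 20.4 in siCDH3, ZEB1 34.7 and 20.6, the collagen-binding protein gene SPARC 19.2 and 12.4, and the keratin gene KRT7 5.49 and 10.2, but the epithelial state genes ERBB3 (11.7 and 8.55) and AP1M2 (6.99 and 5.82) were lower, and the mesenchymal state list had 8 members above and 8 below the median of all genes. The cell cycle genes CCND1 (137 and 92.5) and AURKA (68.9 and 35.3) and the caspase inhibitor gene XIAP (10.4 and 3.81) were lower, and ID2, an inhibitor of helix-loop-helix factors, was higher (9.22 and 36.1). The MHC class I gene HLA-C had 111 and 267, while B2M had 337 and 265. Junction genes CLDN12 (49.7 and 13.7) and OCLN (20.1 and 10.8) were lower.

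In HCC827 the matrix protease gene MMP7 had a TPM of 11.2 in siCTR and 20.2 in siCDH3, the calprotectin genes S100A8 17.7 and 26.7 and S100A9 1218 and 1551, and the sterol reductase gene DHCR7 49.8 and 86.7. The immediate early gene IER2 had 10.3 and 29.8 and the ERK inhibitor gene SPRY1 12.5 and 25.5. Lower were MYC (20.3 and 14.5), the mitophagy receptor gene BNIP3L (44.3 and 19.7), S100A13 (49.5 and 21.4) and ID2 (28.6 and 10.9). CLDN12, ERBB3 and S100A13 overlap a read-through gene, so their TPM is uncertain. All of these come from 1 library per group.

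An siRNA can lower other transcripts through matches to its seed in their 3' UTRs, so short words were examined over 8996 genes with the trend on 3' UTR length and GC removed, and genes with a match to AAGATCAA were lowest over both lines (4 of 1000 shuffles gave a word as low), at mean log2 ratios (± SEM over genes) of -0.05 ± 0.02 in H1299 and -0.06 ± 0.02 in HCC827 for the 291 with all 8 bases, -0.02 ± 0.01 and -0.03 ± 0.01 for the 822 with the first 7, and -0.05 ± 0.02 and 0.02 ± 0.01 for the 427 with the last 7. Genes with a match to TCGGAGAA, which ranked 1 in HCC827 and 147 in H1299, were highest (14 of 1000 shuffles as high), at 0.15 ± 0.04 and 0.12 ± 0.06 for the 51 with all 8 bases, 0.01 ± 0.03 and 0.06 ± 0.03 for the 132 with the first 7, and 0.05 ± 0.03 and 0.06 ± 0.02 for the 165 with the last 7. Base composition stays open. The lowest and highest 8-base words of each line were placed in the other line among words with the same composition. Of these 4 words, 2 lay beyond the central 95% and the others inside. Inside were GAAGATCA, lowest in HCC827, and GCGCAACA, highest in H1299. Beyond were AAGATCAA, placed in HCC827, and TCGGAGAA, placed in H1299, the lowest and highest words over both lines. A candidate explanation, as a hypothesis, is a seed site of the CDH3 siRNA for the lowest word, which occurs in the longest CDH3 transcript as in 11.6% of 2938 genes of similar length, and one of the control siRNA for the highest, but the siRNA sequences were not used here. Taken per line, the lowest 7-base word did not lie beyond shuffles (15 of 100 as low in H1299, 40 of 100 in HCC827), the lowest in HCC827 ranked 21 of 16150 in H1299 but the lowest in H1299 ranked 7787 in HCC827, the highest words differed but lay beyond most shuffles (CAATCCA in H1299, 2 of 100 as high; CGGAGAA in HCC827, 4 of 100), and 3 of 11 genes lower in both lines had a match to AAGATCAA against 17.1% of all genes, too few to tell whether seed matches bear on those genes.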
